A study of Arabidopsis thaliana with 6 samples.

How the data were processed

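Total RNA had been sequenced from 14-day-old Arabidopsis thaliana seedlings grown in long days, per the labels, in 6 libraries: 3 of the wild type (WT) and 3 of the pkl mutant. PKL (PICKLE) encodes a chromatin remodeler of the CHD3 type. The labels give total RNA from whole seedlings and an Illumina library preparation; they do not state the pkl allele, the strandedness of the libraries, the time of harvest, or whether replicates were separate cultures.

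Reads had been aligned with TopHat and assembled and tested with Cufflinks 2.1.1 and Cuffdiff 2.1.1 on the TAIR10 genome, per the submitters' processing notes. The values used here were in 1 deposited table of differential expression with 2896 loci. Expression was in FPKM (fragments scaled by transcript length and by the number of mapped fragments), with 1 value per genotype that combined its libraries, per the file headers. The log2 fold change in the deposited table was the log2 of the pkl value over the WT value, and it matched the same ratio computed from the 2 FPKM columns to within 1.2e-05. The table also held the authors' test statistic, a signed score, which was not used further. The deposited p-value of each locus was a multiple of 5e-05, which was also the smallest value listed, and the deposited q-value was the p adjusted by the authors over all of their tests. No values per library were used, so no spread between replicates, standard error or library size could be given, and the depth of each library is unknown. Each FPKM printed is the authors' group value.

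Every locus in the table was marked as changed by the authors, with q-values in the authors' deposited table of up to 0.0499, and every one was lower in pkl than in WT. The table was therefore 1 side of the comparison, and loci higher in pkl were not analysed here. The number of tests behind the q-values was recovered from the table itself. Under the Benjamini-Hochberg adjustment, the ratio of p to q equals the rank of the p divided by the number of tests. Every whole number of tests from 2896 to 38999 was tried, and the number was sought that made all 284 ranks whole. The ranks came out within 0.017 of whole numbers for 19554 tests, against 0.311 for the next best number, 19555. Multiples of 19554 would also give whole ranks, but the next one, 39108, would exceed the 38094 genes of all kinds in the reference annotation. On simulated data, tables with p-values in the same steps and with lower loci alone returned the true number of tests in 20 of 20 tables, and the true number of passing tests in 20 of 20.

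Gene identifiers were taken from the table and paired with symbols and products through the RefSeq annotation of TAIR10.1, in which 3024 of 3033 identifiers had an entry. A locus could hold several genes merged by the assembly, as 141 of the 2896 did; another 13 had no gene identifier. Where a gene named in the text shared a locus with another gene, the value is that of the locus. Starts in the table were counted from 0 and are printed counted from 1. All 2740 loci of 1 gene that could be compared overlapped their gene in the annotation. Genes were taken to have a near-identical copy where the longest coding sequence aligned to that of another gene at 95% identity or more over at least 80% of its length (BLAST+ 2.17.0, megablast).

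A total of 20 gene lists, with 337 genes, and the rule for the genes named were fixed before the data were examined. The rule took PKL, up to 4 listed members with the largest change per gene list, the 10 genes with a symbol and at least 1 FPKM in WT that had the largest fold, and the 5 genes with the highest level. The planned test compared the share of changed members between a list and all other genes in the table, or the split of higher and lower members. Neither could be run on a table of lower loci alone. In its place, the number of list members in the table was compared with the 2896 lower loci of 19554 tests by Fisher's exact test, one-sided for more members than chance, with Benjamini-Hochberg adjustment over the 20 lists. Which genes outside the table had been tested was not known, so every member was counted as tested, which lowers the share and makes the test stricter. A low share of a list was therefore not interpreted. Members in 1 locus counted once. The median log2 fold change of listed members was also placed among 10000 random draws of loci from the table, matched in 10 bins of expression. With the p-values adjusted over the list alone, absent members were given a p of 1. On simulated lists of the real sizes, at least 1 list was called by chance in 2.9% of 1000 sets, and a list of 20 genes with 50% of its members lower was called in 75.1%. The simulated genes were independent and equally likely to be lower, as the test assumes. The simulation thus checks the calculation alone. It cannot show how the test behaves for real lists, whose genes can change together and differ in level.

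Alternatives were a q threshold of 0.01, a fold of at least 2, FPKM minimums of 1 and 5 in WT, other adjustments for multiple tests, nuclear protein-coding genes alone, and pseudocounts of 0.1 and 1. An annotated background and the removal of merged loci were added after the data were seen, as were the tests of annotation terms and gene families and the binomial test of list members against the share of lower loci among passing tests. Computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.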

Results

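The transcriptomes of 14-day-old long-day seedlings were compared between the wild type (3 libraries) and the pkl mutant (3 libraries), to find genes whose transcript level depends on the chromatin remodeler PICKLE. The values were the authors' FPKM, 1 per genotype and locus, so they carry no error of their own here, and the depth of the libraries is unknown. Coordinates are those of the TAIR10 build.

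The PKL transcript (AT2G25170, chromosome 2, positions 10712606 to 10723986), the product of the mutated gene, was lower in the mutant. It stood at 19.2 FPKM in WT and 6.79 FPKM in pkl, a 2.84-fold difference (log2 fold change -1.50). Its q-value in the authors' deposited table was 0.000338. A transcript remained in the mutant, and the table does not show whether it could encode a working protein.

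The pkl seedlings had lower transcript levels than WT at 2896 loci, led in level by genes of the photosynthetic light-harvesting antenna and of the photosystems. Most differences were under 2-fold. The median locus was 1.52-fold lower in pkl, with quartiles at 1.32-fold and 2.02-fold, and 1383 loci (47.8%) differed by less than 1.5-fold. A difference of at least 2-fold was present at 748 loci (25.8%) and of at least 4-fold at 132. Levels in WT ran from 0.478 to 11129 FPKM, with a median of 16.8 FPKM, and no locus was at 0 in either genotype.

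These lower loci were 14.8% of the 19554 tests that the authors' p-values and q-values imply. In all, 5992 tests (30.6%) had a p-value as low as the largest in the authors' deposited table, 0.0153. The other 3096 of them were not in the table analysed here and their direction was not analysed. The lower loci were thus 48.3% of the loci that passed.

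**Figure D1:**
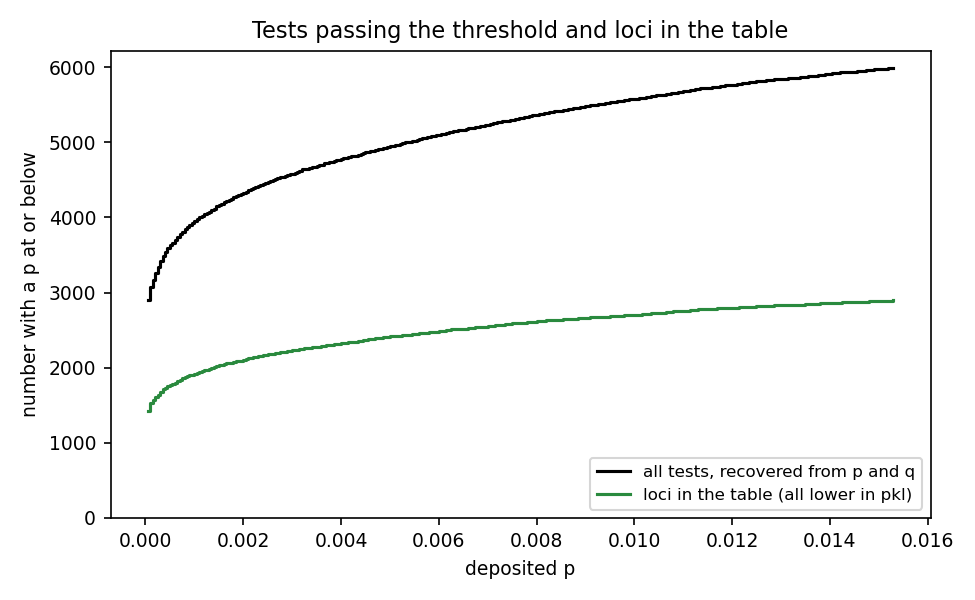
Cumulative number of tests (y axis) with a deposited p-value at or below the value on the x axis, for all tests recovered from p and q (black) and for the loci in the table, all lower in pkl (green). The upper curve ends at 5992 tests and the lower at 2896 loci.

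The 10 named genes with the largest fold covered several functions. RLP19 (AT2G15080), a receptor-like protein, fell from 4.99 to 0.187 FPKM, which was 26.7-fold lower in pkl. The tonoplast aquaporin gene TIP2;3 (AT5G47450, chromosome 5, positions 19248249 to 19249504) fell 24.9-fold, from 65.5 to 2.63 FPKM. PGL5, annotated as a 6-phosphogluconolactonase, was 20.9-fold lower, and FAMT, a farnesoic acid methyltransferase, was 17.7-fold lower. Both were low in WT, at 2.07 and 1.41 FPKM. MIOX4, a myo-inositol oxygenase, was 11.8-fold lower, the helicase gene MEE29 10.9-fold lower and UMAMIT17, of a family of amino acid transporters, 10.6-fold lower. MIOX4 and MEE29 were also low in WT, at 1.84 and 1.96 FPKM. The germin-like gene GER2 and IPS1, a non-coding transcript induced by phosphate starvation, were 8.24-fold and 8.23-fold lower. The plasma membrane aquaporin gene PIP2;4 fell 7.61-fold, from 37.2 to 4.89 FPKM. GER2 has a near-identical coding copy, AT5G39160, so its reads could not be assigned with certainty. Among genes without a symbol, which the naming rule left out, the glutaredoxin-like gene AT3G62950 had the largest fold in the table, 34.1, from 44.4 to 1.3 FPKM. The q-values of these genes in the authors' deposited table ranged from 0.000338 to 0.0402.

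**Figure D2:**
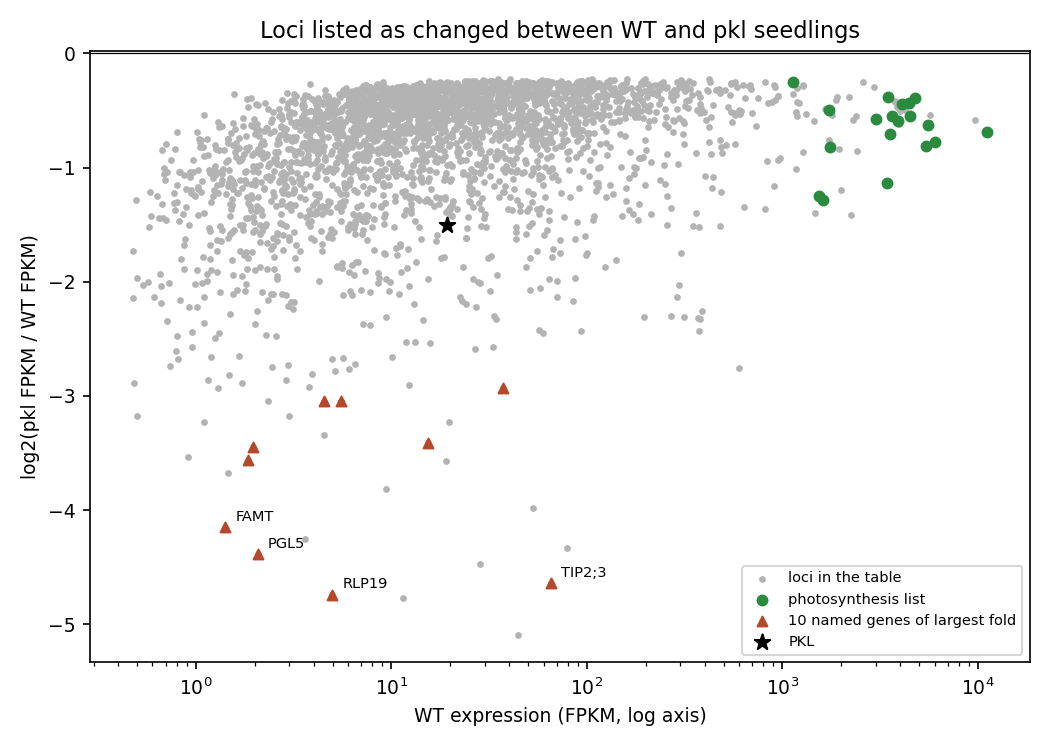
Log2 ratio of pkl over WT expression (y axis) against WT expression in FPKM (x axis, log scale) for the 2896 loci in the table, with the photosynthesis list (green circles), the 10 named genes of largest fold (triangles) and PKL (star). The photosynthesis genes lie at the right, above 1000 FPKM in WT, mostly at folds under 2, and the genes of largest fold lie mostly at low levels.

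Many genes of photosynthesis were lower in pkl. Of the 27 genes in that list, 19 (70.4%) were in the table, where 4.0 would be expected from the share of all tests (Fisher's exact test, one-sided, adjusted p = 2.2e-09). Within the list, the largest folds were in the antenna proteins of photosystem II. LHCB2.1 fell 2.43-fold, from 1616 to 665 FPKM, LHCB2.2 fell 2.37-fold, LHCB1.4 fell 2.2-fold and LHCB4.2 fell 1.76-fold. LHCB2.3, which was not in the list, fell further, by 2.84-fold, from 480 to 169 FPKM. All 4 photosystem I antenna genes of the list fell, LHCA4 by 1.76-fold, LHCA1 by 1.72-fold, LHCA3 by 1.63-fold and LHCA2 by 1.46-fold. Reaction centre subunits PSAD1 and PSAF, the oxygen-evolving proteins PSBO2 and PSBP1, and RBCS2B, a small subunit of Rubisco, were also lower, by 1.19-fold to 1.49-fold. The median fold of the 19 was 1.51, at percentile 3.88 of random draws of listed loci with matched expression, where low percentiles mean larger falls. The draws held only loci that had passed the authors' test. The fall needed to pass differs between loci, so selection alone can lower a percentile. No adjustment over the lists was made, and lists without enrichment were as low: 2.14 for jasmonate and ethylene defence and 3.97 for vegetative phase change. The q-values of the 19 in the authors' deposited table ranged from 0.000338 to 0.0456.

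The 5 lower genes with the highest level were of the same kind. LHCB1.5 stood at 11129 FPKM in WT and 6899 FPKM in pkl, 1.61-fold lower. PSBR, a subunit of photosystem II, fell 1.5-fold from 9634 FPKM, and PSAO, a subunit of photosystem I, fell 1.45-fold from 5667 FPKM. LHCA1 fell from 6035 to 3517 FPKM and LHCB1.1 from 5524 to 3575 FPKM. Near-identical copies limit the assignment of reads for LHCB1.1, LHCB2.1, LHCB2.2 and RBCS2B, and the loci of LHCB4.1 and PSBP1 each hold a neighbouring gene. The direction of the other 8 listed genes was not analysed here, so a shared direction of the list is not shown. If all 27 had passed, the case least favourable to such a direction, the share of lower members did not pass the test against that of all passing tests (exact binomial test, one-sided, p = 0.0172, adjusted p = 0.345). The enrichment rests on falls under 2-fold: with a minimum of 2-fold, 3 members were left (adjusted exact p = 0.544).

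**Figure D3:**
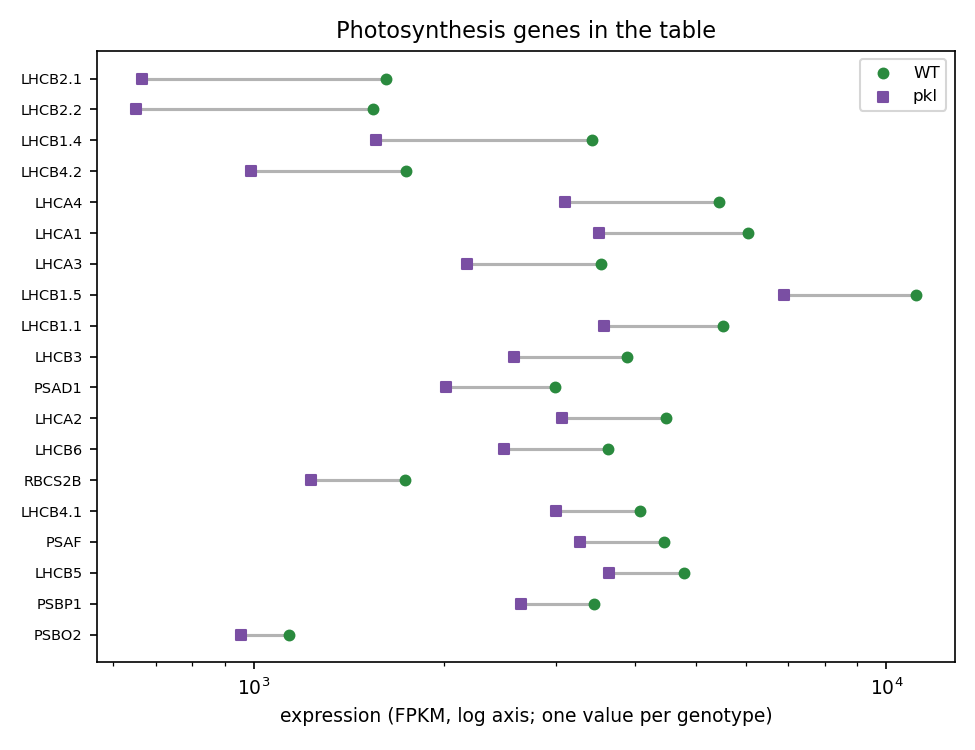
Expression in FPKM (x axis, log scale) in WT (green circles) and pkl (purple squares) of the 19 genes of the photosynthesis list in the table, 1 value per genotype. All lie lower in pkl, from 2.43-fold for LHCB2.1 to 1.19-fold for PSBO2.

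Several genes of the cold and dehydration response were lower too. The list had 8 of 17 loci in the table against 2.52 expected (Fisher's exact test, one-sided, adjusted p = 0.0159); RD29A and RD29B share 1 of these loci. The direction of the other members was not analysed here, so a shared direction of the list is not shown either. If all 17 loci had passed, 8 lower ones would be no excess over the share among all passing tests (exact binomial test, one-sided, p = 0.634, adjusted p = 1.0), and fewer passing loci would lower that p. COR15B, which protects chloroplast membranes in the cold, fell 3.10-fold, from 2.98 to 0.961 FPKM. KIN1 fell 2.67-fold, the NAC transcription factor gene RD26 fell 2.66-fold, from 20.2 to 7.60 FPKM, and CBF2, a transcription factor of the cold response, fell 2.53-fold. The dehydrin gene COR47 fell from 438 to 194 FPKM. The median fold was 2.40, at percentile 0.27 of matched draws, which again held only loci that had passed, so the same limits apply. KIN1 and KIN2 are near-identical copies of each other, and both were lower. In the authors' deposited table the q-values of these loci ranged from 0.000338 to 0.0308.

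Circadian clock genes were in the table in 7 of 17 cases, and the adjusted p for the list was just past the threshold (Fisher's exact test, one-sided, 0.0513). PRR5 fell 2.58-fold, from 41.5 to 16.1 FPKM, PRR9 fell 2.03-fold, LNK2 fell 1.76-fold and CCA1 fell 1.62-fold, and PRR7, CHE and GI fell less. PRR9 and CCA1 were near 1 FPKM in both genotypes, and PRR7 shares its locus with the kinase gene CDL1. Of the light signalling list, 3 of 9 members were in the table (adjusted exact p = 0.547): PIF4 fell 1.74-fold, from 61.3 to 35.2 FPKM, HFR1 fell 1.42-fold and PIF5 fell 1.32-fold.

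Among markers of root tissue, 7 of 22 genes were lower in pkl, a share of 31.8% that did not pass adjustment (Fisher's exact test, one-sided, p = 0.0345, adjusted p = 0.173). THAD, an enzyme of the root triterpene thalianol pathway, fell 3.3-fold, from 8.14 to 2.47 FPKM. The iron transporter gene IRT1 fell 2.04-fold and CASP1, which builds the Casparian strip of the endodermis, fell 1.94-fold, from 48.5 to 25 FPKM. CASP2, THAS and the root hair gene COBL9 were lower as well, but CASP2 shares its locus with SPY. None of the 5 markers of pollen was in the table.

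Lists tied to known roles of PKL in seed and embryo identity had no member in the table: 0 of 11 regulators of seed maturation and embryo identity, 0 of 18 genes of seed storage, oil body and late embryogenesis proteins, and 0 of 15 genes of Polycomb repressive complexes. Their levels were not analysed here, so neither a higher level nor an unchanged one in pkl can be read from this. Of the 15 genes of other chromatin remodelers, H2A.Z deposition and histone deacetylases, 1 was in the table: PKR1, a close relative of PKL, fell 1.3-fold, from 8.56 to 6.61 FPKM.

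Of the vegetative phase change list, 3 of 19 members were lower (adjusted exact p = 1.0). SPL4 fell 3.19-fold and SNZ fell 3.15-fold, both from low levels (4.44 to 1.39 FPKM and 2.31 to 0.732 FPKM). TOE1 fell 1.46-fold, from 30.5 to 20.9 FPKM. Of 20 flowering time genes, 3 were lower (adjusted exact p = 1.0). The floral repressor genes SVP and MAF3 fell 1.98-fold and 1.47-fold, and SOC1, which promotes flowering, fell 1.5-fold, from 17.7 to 11.8 FPKM. Of 11 floral organ identity genes, only SEP3 was in the table, 3.38-fold lower, from 9.28 to 2.75 FPKM. Of 10 genes of the shoot meristem and organ boundaries, only CUC2 was in it, 2.65-fold lower and under 1 FPKM in both genotypes.

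Of 26 genes of gibberellin metabolism and response, 4 fell (adjusted exact p = 1.0): GA3OX1, an enzyme of the last step to active gibberellin, fell 2.22-fold, from 9.06 to 4.09 FPKM, GA2OX2, which inactivates gibberellin, fell 1.66-fold, the receptor gene GID1C fell 1.42-fold and GASA6 fell 1.26-fold. Of 19 auxin genes, only IAA14 was in the table, 1.33-fold lower. Of 19 genes of jasmonate and ethylene defence, 4 fell (adjusted exact p = 0.878): TAT3 fell 11.6-fold from 0.907 FPKM, the repressor gene JAZ9 fell 4.02-fold, from 28.5 to 7.09 FPKM, and the jasmonate synthesis genes AOS and OPR3 fell 1.72-fold and 1.34-fold. Of 20 genes of salicylic acid and defence, WRKY70 fell 3.63-fold and the regulator gene NPR1 fell 1.33-fold.

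Of 16 genes of glucosinolate synthesis, 4 were lower (adjusted exact p = 0.678). MYB29, a regulator of aliphatic glucosinolates, fell 7.41-fold from 1.71 FPKM, MAM1 fell 1.60-fold, CYP79B3 fell 1.35-fold and MYB51 fell 1.3-fold. Of 20 genes of flavonoid and anthocyanin synthesis, 2 were lower (adjusted exact p = 1.0): MYBL2, a repressor of anthocyanin synthesis, fell 3.29-fold, from 67.2 to 20.4 FPKM, and MYB12, an activator of flavonol synthesis, fell 1.82-fold.

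With p-values adjusted over the list alone, 19 photosynthesis genes, 9 of cold and dehydration, 7 of the clock, 7 root markers and 3 of light signalling passed. Those 5 counts were fixed in advance, because no p-value in the authors' deposited table exceeds 0.0153. Adjusted over the list alone, the members in the table of the other lists passed too, except IAA14 and CUC2.

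**Figure D4:**
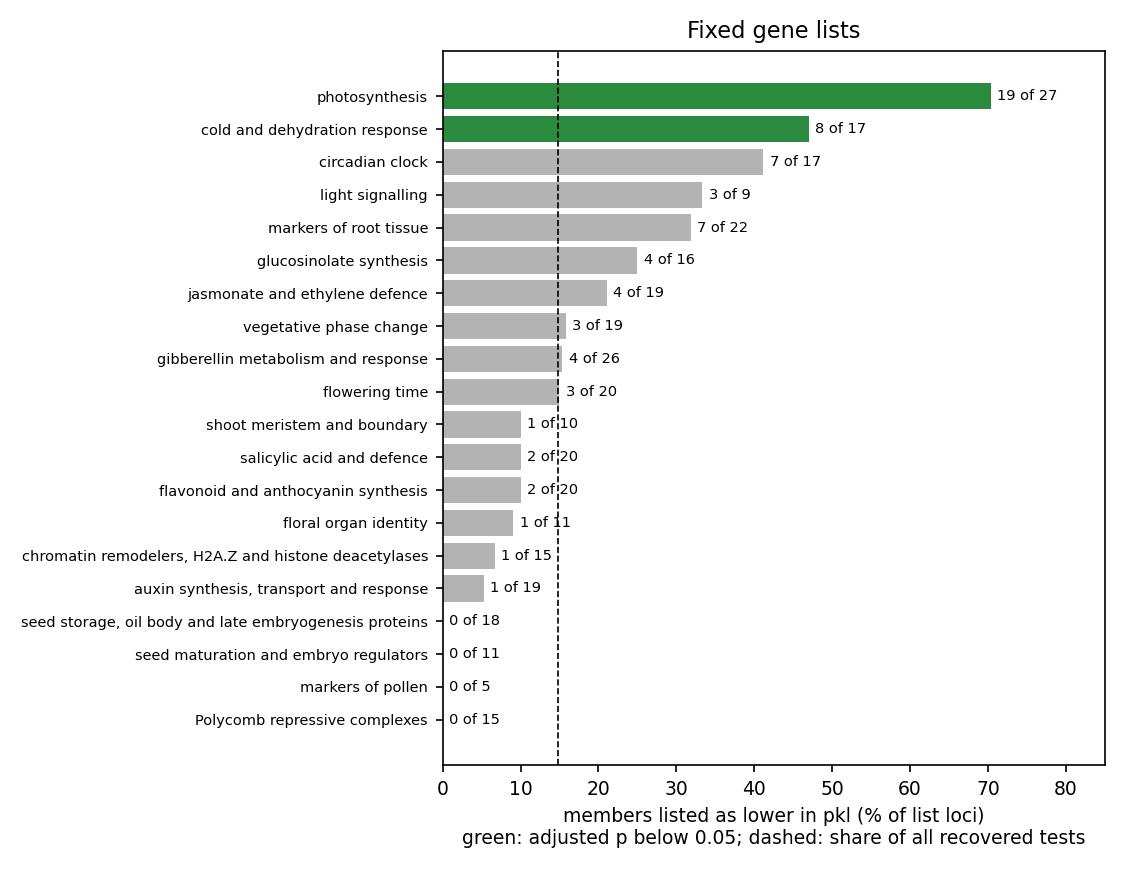
Share of each gene list in the table, all lower in pkl (x axis, percent of list loci; counts beside the bars), for the 20 lists. The dashed line marks 14.8%, the share of all recovered tests, and the lists with an adjusted p under the threshold (green) are photosynthesis and the cold and dehydration response.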

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

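The annotated background and the removal of merged loci were chosen after the data were seen. Of the loci lower in pkl, 748 were left with a minimum of 2-fold, and between 2145 and 2829 with a q under 0.01, a level of at least 1 or 5 FPKM in WT, or nuclear protein-coding genes alone. Bonferroni adjustment left 0, because the smallest p listed, 5e-05, is too large for 19554 tests. Adjustment over the listed loci alone and leaving out loci at 0 removed none, which the make-up of the table fixes. The 5992 tests passing became 4402 at q under 0.01. PKL stayed lower with pseudocounts of 0.1 and 1 (log2 fold change -1.49 and -1.38). Medians of lists with weakly expressed members shrank with a pseudocount of 1. The median log2 fold change went from -1.66 to -0.933 for vegetative phase change and from -1.39 to -0.784 for jasmonate and ethylene defence. With the 2-fold minimum the photosynthesis list had 3 members (adjusted exact p = 0.544) since most of its falls were smaller, and the other 19 lists kept their side of the threshold. With a minimum of 1 FPKM the clock list, with 7 members, passed (adjusted exact p = 0.045), as fewer loci were then counted as lower. That minimum was applied to the lower loci alone, and the 19554 tests were kept. The p therefore falls for any list that loses no member, and this pass adds nothing on the clock genes. Against annotated protein-coding genes the clock list (7 members, adjusted exact p = 0.00818) and the root markers (7 members, adjusted p = 0.0332) passed as well, as that background is larger. All 20 lists kept their side at q under 0.01 and without merged loci. The recentring on all expressed genes, other normalizations and leaving out each replicate were not run, since they need loci outside the table or values per library. No paired analysis was possible because the table has 1 value per genotype, and other splits of the libraries could not be formed for the same reason.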

Other observations

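All tests in this part were chosen after the data were seen, except the Fisher's test of the root marker list against the 19554 tests. Beyond the fixed lists, transcripts of many plasma membrane water channels were lower in pkl. Of 12 genes annotated as plasma membrane intrinsic proteins, 9 were lower (Fisher's exact test, one-sided, against the 19554 tests, adjusted p = 0.00198 over 406 product families). Besides PIP2;4, PIP1C fell 2.32-fold, from 487 to 210 FPKM, PIP1A fell 2.11-fold and PIP3 fell 1.92-fold, from 833 to 435 FPKM. Of 8 annotated tonoplast intrinsic proteins, a family too small for that test and looked up after TIP2;3 was seen, 5 were lower, among them TIP2;2, which fell 4.92-fold from 268 FPKM, and TIP2, which fell 1.81-fold from 2400 FPKM. CBL-interacting protein kinases, which relay calcium signals to ion transporters, were lower in 11 of 19 cases (adjusted exact p = 0.00356), with CIPK20 falling 4.50-fold, from 22.9 to 5.08 FPKM. Response regulators of cytokinin signalling were lower in 11 of 23 cases (adjusted exact p = 0.0239). They included 7 of the 10 type-A regulators, whose transcripts cytokinin induces. ARR15 fell 5.52-fold, ARR6 fell 3.09-fold, from 43.2 to 14.0 FPKM, RR5 fell 2.49-fold and ARR7 fell 2.32-fold. The q-value in the authors' deposited table was 0.0126 for ARR15 and 0.000338 for ARR6, RR5 and ARR7. RR1, RR2, RR12 and ARR11, outside the type-A group, were lower too, with log2 fold changes from -0.244 to -0.946. Of 50 genes annotated as thioredoxin superfamily proteins 16 were lower, which did not pass adjustment (adjusted exact p = 0.158). The call depends on the background: against annotated protein-coding genes these passed (adjusted exact p = 0.00354), and 8 families passed in place of 3. They held AT3G62950, its neighbour AT3G62960 and the 5 adjacent glutaredoxin-like genes from AT4G15660 to AT4G15700.

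Among 386 annotation terms with at least 10 genes, 13 were enriched among the lower loci by the same test, adjusted over the terms. Photosynthesis led, with 36 of 67 genes (adjusted exact p = 4.5e-11), followed by the chloroplast thylakoid membrane with 72 of 208 (adjusted p = 1.4e-10). Terms outside the chloroplast and light response were microtubule-based movement with 17 of 47 genes (adjusted exact p = 0.0142; median fold 1.4), amino acid transport with 11 of 24 (adjusted p = 0.0142), response to water deprivation with 23 of 77 (adjusted p = 0.0215; median fold 1.71) and the apoplast with 48 of 212 (adjusted p = 0.044). A gene can carry several terms, and the genes that these terms share with those of the chloroplast were not counted. The water deprivation genes included PIP1C and PIP1A, the NAC gene NAC3, which fell 5.78-fold, and XTH6, which fell 2.78-fold. Against annotated protein-coding genes, a larger background, 30 terms were enriched, so the number of terms depends on the background.

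The number of lower genes in the photosynthesis list was weighed against 3 technical explanations. Reads shared between near-identical copies do not account for it, since the members without such a copy were lower in 15 of 20 cases (Fisher's exact test, one-sided, p = 2.59e-09). High read numbers, which make small changes pass in either direction, stay open: if all 27 members had passed, the case least favourable to a shared direction, 19 or more lower ones at the 48.3% share of passing tests had a p of 0.0172 (exact binomial test, one-sided), and 0.345 after adjustment over the 20 lists. A larger share of root tissue in pkl samples also stays open, since the 7 of 22 root markers that were lower did not pass adjustment (Fisher's exact test, one-sided, adjusted p = 0.173) and the others were not analysed here. Lower expression of the antenna genes in pkl leaves was not tested, nor was a difference in growth stage or time of harvest between the genotypes.

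The lower clock genes may reflect a shift in the clock's phase or in the time of harvest. Of 8 genes placed as peaking from dawn through the day, 5 were lower (CCA1, LNK2, PRR9, PRR7 and PRR5). Of 8 placed as peaking from afternoon to evening, 1 was lower (GI). The difference did not pass the threshold (Fisher's exact test, two-sided, p = 0.119). Placing CHE, whose phase was left open, with the day genes gave an exact p of 0.0498, so the outcome changes with how a gene is placed. Other placements, such as PRR5 with the afternoon genes, were not tested. The split cannot decide on a phase shift, because without the time of harvest the direction expected for each group is unknown. Time of harvest and genotype cannot be told apart here, for these genes or for any other list, since the labels give no time.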
